A study of Drosophila sechellia and Drosophila simulans with 8 samples.

How the data were processed

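RNA from bodies of adult females was measured on 8 Affymetrix arrays that carry probe sets designed for Drosophila melanogaster. Per the labels' protocols, flies were raised at 25 °C on a yeast and cornmeal medium, total RNA was isolated with TRIzol and column purification, and biotin-labelled cRNA was made from 7 micrograms of it. The labels give 4 groups of 2 arrays: D. sechellia and D. simulans, each under choice and under no choice for a blend of octanoic and hexanoic acid. What the flies could choose between, for how long and at which age is not given in the sources used here. The labels number the arrays of a group 1 and 2 and do not say whether they come from separate flies or from separate RNA.

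The deposited values are linear probe-set signal, an intensity, made with MAS5 per the submitters' processing notes, which give no version and no settings. The deposited intensities are already scaled: with 2% of values trimmed at each end, the mean signal was 500 on each of the 8 arrays, within the 5% set as the limit for using the values as deposited. They were therefore taken to log2 with no further scaling. The arrays' number, 2 per group, limits the precision of every value.

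Of 18952 probe sets, 183 control probe sets were left out of the tests, as was the 30% of the remainder with the lowest mean log2 signal, below a geometric mean signal of 49.9. The tests used the 13138 probe sets left. In the probe annotation, which gives D. melanogaster gene symbols, 13647 probe sets carried 1 symbol, 402 carried several and 4720 carried none. Among the tested probe sets, 10470 carried 1 symbol and stood for 9562 genes. None of the annotation's gene identifiers occurs in the D. sechellia gene table, so symbols are those of the D. melanogaster annotation and no position is given.

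The 4 groups were fitted as cell means with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), without covariates and without a replicate block, with 4 residual degrees of freedom. Contrasts were the species difference (sechellia minus simulans) averaged over treatments, in no choice and in choice, the choice effect (choice minus no choice) averaged over species, in sechellia and in simulans, and the interaction, which is the choice effect in sechellia minus that in simulans. Probe sets with a Benjamini-Hochberg adjusted p below 0.05 are called. Errors printed with log2 differences are standard errors from this fit. Where every array of a group lay below the median of its Bacillus controls, taken as background, a change in a gene named in the text is a bound; signals were then raised to that median and the smaller change is printed as a bound over background, a step added after seeing the data.

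Array 1 of sechellia choice stood apart from the other 7 arrays, so every fit was also made without it, a choice made after seeing the data. In that fit, called 7 arrays here, 3 residual degrees of freedom remain, and the sechellia choice group rests on its array 2 alone, which is assumed to vary like the arrays of the other groups. The dim filter and the probe sets were kept as with 8 arrays.

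Lists of genes were fixed by patterns of gene symbols: odorant-binding proteins, odorant receptors, gustatory receptors, ionotropic receptors, cytochrome P450, glutathione transferases, UDP-glycosyltransferases, carboxylesterases, the Osiris family, antimicrobial peptides, immune recognition proteins, heat shock proteins, Turandot stress peptides, digestive trypsins and Jonah proteases, amylase and maltases, lipid storage and fatty acid metabolism, vitelline membrane and chorion, yolk proteins and their uptake, female germline, male reproductive markers, head and eye markers, neuronal genes, the dopamine pathway, the circadian clock, flight and body muscle, fat body and haemolymph, insulin and nutrient signalling, juvenile hormone and ecdysone, ribosomal proteins, the proteasome, oxidative phosphorylation, cuticle proteins, and DNA replication and cell cycle. Some genes are in more than 1 list; tobi is in the maltase and the insulin list. The patterns also took in members that do something else: Cp190 and Cp110 in the chorion list are centrosomal proteins, and Acp65Aa in the male list is a cuticle protein. The 33 lists were tested with limma's camera with a preset correlation between genes of 0.01, using the brightest probe set of each gene, with adjustment over the lists. Camera with an estimated correlation and limma's fry were run beside it. The preset value treats genes as nearly independent. When the arrays were regrouped wrongly between species, in a fit of 2 groups, it called a median of 14 lists with 8 arrays and 3 with 7. Camera's p-values with the preset value may therefore be too small here, also where 1 array stands for sechellia choice. Camera compares a list with all other tested genes, so a list is higher or lower relative to these. Members past the threshold are counted both after adjustment over all tested probe sets and adjusted over the list alone.

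Named genes come from probe sets with 1 symbol. For the species difference averaged over treatments they are the 10 largest differences in each direction among called probe sets whose arrays of the 2 species do not overlap. For each choice effect and the interaction they are the 10 largest called changes in each direction, and the 5 with the smallest p where fewer than 5 were called. From each list that passed its test or had a called member, up to 4 members with the smallest p were added, as were genes fixed in advance and the 3 brightest male and head markers. The text names part of them. Of the genes fixed in advance, Obp57d, Obp83a and Act5C have no probe set with their symbol alone, and Obp57e, lush, Or22a, Osi7 and Osi8 lie below the dim filter, so none of these was tested; no Hsp70 gene was among the tested genes with 1 symbol. Comparisons, tests, gene lists, the rule for named genes and all alternatives other than those said to be added later were chosen before the data were examined.

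The fit was tested on simulated arrays with the spread of the real ones, in which 100 of 13138 probe sets were changed 2-fold and 100 were changed 4-fold. Array 1 of sechellia choice was given a wider spread, the same for every probe set and without a shift. On the real array dim signals stood higher and bright signals lower than on the others, which was not simulated. Recovery and false calls with 8 arrays therefore do not cover that feature. With 8 arrays it recovered 35% of the 4-fold changes for the species difference averaged over treatments, 18% for the species difference in choice, 39% for the choice effect averaged over species, and 0% for the other 4 contrasts, where limma's adjusted p reached the threshold for no changed probe set; of the 2-fold changes it recovered 4% for the choice effect averaged over species and 0% elsewhere. With 7 arrays it recovered 76% of the 4-fold changes for the species difference averaged over treatments, 62% in no choice, 69% in choice, 76% for the choice effect averaged over species, 60% in sechellia, 69% in simulans and 55% for the interaction; of the 2-fold changes it recovered 49%, 42%, 34%, 47%, 35%, 41% and 17% in the same order. At most 6 of 12938 unchanged probe sets were called. For the lists, genes were simulated as independent and without the wider spread of array 1 of sechellia choice. A shifted list was then called in each of the 5 list comparisons over 9562 genes, and no list that shares no gene with it. This does not test camera on correlated genes or on an array that stands apart.

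Alternatives were median centring, quantile normalisation and cyclic loess between arrays, no dim filter and one that leaves out 50%, an offset of 12.5 signal units (the 10th percentile) before log2, no intensity trend, a robust fit, array weights, a replicate block, only the arrays compared, no probe sets with a suffix that marks possible cross-hybridisation, the mean of a gene's probe sets in the list tests, and leaving out each array in turn. Scalings, filters and list tests with 7 arrays and a crossed replicate block were added after seeing the data. Choice effects of the 2 species share no array and were compared across probe sets by correlation, with no p since genes are not independent replicates.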

Results

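Expression in the bodies of adult females was compared between Drosophila sechellia and Drosophila simulans, each held with and without a choice for a blend of octanoic and hexanoic acid. D. sechellia is a specialist on the fruit of Morinda citrifolia, which is rich in both acids, and D. simulans is its generalist relative. The series names the question as a design of species by choice. There were 4 groups of 2 arrays: sechellia no choice, sechellia choice, simulans no choice and simulans choice. Apart from array 1 of sechellia choice, the median signal lay between 111 and 129.8 and arrays of the same group correlated at Pearson r 0.963 to 0.969 across 13138 probe sets. The p-values measure the spread between these samples, which may be technical, because the labels only number them. With 2 arrays per group, the number of arrays limits the precision. Both species hybridised to probes designed for D. melanogaster, so a difference in sequence can change a signal as a difference in RNA does.

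Array 1 of sechellia choice stood apart from the other 7. Its correlation with the other sechellia arrays was 0.712 to 0.720 and with the simulans arrays 0.674 to 0.696, where sechellia and simulans arrays otherwise correlated at 0.912 to 0.918. Its range of signal was narrow, from 81.0 at the 10th percentile to 3237 at the 98th, against 10 to 12.2 and 6128 to 6359 on the others. The SD of its log2 signal was 1.39, against 2.06 to 2.15. Its Bacillus control probe sets, which no fly RNA matches, had a median signal of 128.85 over 24 probe sets, 4.59 times the highest of the others. Each comparison is therefore given with 8 arrays and without this array, as 7 arrays. All probe sets called with 8 arrays were also called with 7, in the same direction.

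**Figure D1:**
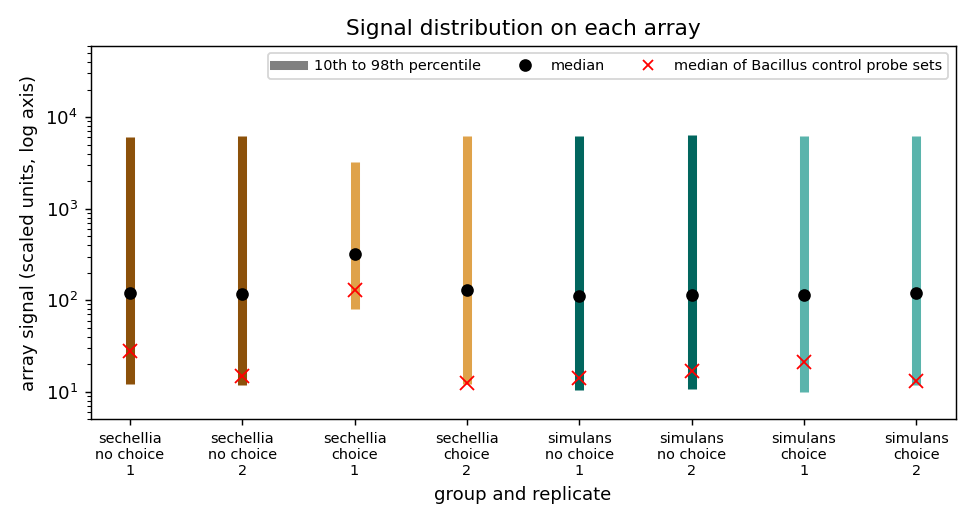
Probe-set signal on each of the 8 arrays (log axis, signal units), with bars from the 10th to the 98th percentile, dots at the median and crosses at the median of the 24 Bacillus control probe sets. Array 1 of sechellia choice has a shorter bar, from 81.0 to 3237, and a control median of 128.85, 4.59 times the highest of the others.

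Digestive protease genes were among the largest species differences and were lower in sechellia. Averaged over treatments, Jon65Aiv, a Jonah serine protease of the midgut, differed by log2 -8.54 ± 0.21 (SE, n = 4 arrays per species; adjusted p = 1.2e-06) and by -7.66 or lower over background, and Acbp5, of the acyl-CoA-binding protein family, by -7.83 ± 0.15 (adjusted p = 2.7e-07). The trypsins epsilonTry, betaTry and alphaTry differed by -6.84 ± 0.37, -5.24 ± 0.28 and -3.72 ± 0.18, and the Jonah proteases Jon25Biii, Jon25Bi and Jon74E by -6.51 ± 0.30, -5.53 ± 0.32 and -4.63 ± 0.14. Of 27 digestive trypsins and Jonah proteases, 15 were lower and 5 higher in sechellia with 8 arrays (15 and 6 adjusted over the list alone), and 16 were lower and 6 higher with 7. As a list they were lower (camera adjusted p = 7.1e-06 with 8 arrays, 4.3e-06 with 7; median log2 -1.13 and -1.36), a call lost with an estimated correlation (adjusted p = 0.61 and 0.34). CG17571, CG5568 and CG18180 were also lower, at -6.32 ± 0.26, -5.63 ± 0.25 and -5.45 ± 0.37. On the signal scale Jon65Aiv stood at 13031 to 15647 on the simulans arrays and at 4.6 and 7.9 on the sechellia no choice arrays, below the background controls. CG5568 also lay below them there, and its difference is -5.12 or lower over background.

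Fad2 and eloF were among the 10 largest differences higher in sechellia. Fad2, a desaturase that makes hydrocarbon dienes, was higher by log2 5.28 ± 0.22 (adjusted p = 1.5e-05), the elongase gene eloF by 4.20 ± 0.25 (adjusted p = 7.7e-05) and the desaturase gene Desat2 by 2.81 ± 0.19. Desat1, -0.08 ± 0.27, and the fatty acid synthase gene FASN1, 0.21 ± 0.29, did not pass the test with 8 arrays. FASN1 passed with 7, at 0.46, and Desat1 was 0.16 (adjusted p = 0.058) with 7 arrays and passed after loess scaling of these, at 0.14. Of 44 genes of lipid storage and fatty acid metabolism, 4 were higher and 3 lower with 8 arrays (4 and 3 adjusted over the list alone) and 15 higher and 8 lower with 7, with no shift of the list (camera adjusted p = 0.84 and 0.34). The other genes with the largest positive differences were CG6733 (5.72 ± 0.35), CG15263 (4.90 ± 0.59), drl, a receptor tyrosine kinase gene (4.48 ± 0.19), CG14499 (4.39 ± 0.24), Nazo (4.30 ± 0.49), CG9497 (4.29 ± 0.54), CG31380 (4.08 ± 0.52, at least 3.70 over background) and nompB, of intraflagellar transport (4.01 ± 0.31).

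Eggshell genes were lower in sechellia. Cp18 and Cp16, of the chorion, differed by log2 -2.08 ± 0.31 and -1.88 ± 0.15, the vitelline membrane gene Vm34Ca by -1.67 ± 0.20, and yellow-g and yellow-g2, of the eggshell, by -1.93 ± 0.17 and -2.01 ± 0.25. Of 16 vitelline membrane and chorion genes 10 were lower with 8 arrays (12 adjusted over the list alone), and 13 were lower and 1 higher with 7. The list was lower (camera adjusted p = 4.3e-08 and 2.3e-09; median log2 -1.33 and -1.03; adjusted p = 0.77 and 0.54 with an estimated correlation). The yolk protein genes Yp1, Yp2 and Yp3 gave -0.39 ± 0.37, -0.01 ± 0.38 and 0.12 ± 0.31 with 8 arrays and passed no test there. With 7 arrays Yp3 was higher by 0.31 (adjusted p = 0.02), and Yp2 passed only after quantile normalisation or loess of the 7 arrays, at 0.14 and 0.21. Among 5 genes of yolk and its uptake, 1 was called with 7 arrays, and the list was not shifted (camera adjusted p = 0.39 and 0.94). Of 39 female germline genes, 3 were lower and 1 higher with 8 arrays, and 11 lower and 3 higher with 7 (camera adjusted p = 0.077 and 0.16). The Osiris genes Osi6, -4.03 ± 0.77 (-3.68 or lower over background), and Osi15, -2.46 ± 0.50, were lower. Of 14 Osiris genes 2 were lower with 8 arrays (camera adjusted p = 0.36, median log2 0.05 and mean -0.52) and 6 with 7, where the list was lower at a camera adjusted p of 0.024 (adjusted p = 0.54 with an estimated correlation), a call lost after median centring.

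Odorant-binding proteins differed in both directions. Obp99b was higher in sechellia by log2 3.20 ± 0.25 and Obp44a by 1.20 ± 0.17, and Obp18a, Obp56e and Obp19c were lower, at -4.37 ± 0.78 (-4.08 or lower over background), -2.18 ± 0.23 and -2.10 ± 0.26. Of 22 members, 3 were higher and 3 lower with 8 arrays (5 and 3 adjusted over the list alone) and 5 and 5 with 7 (camera adjusted p = 0.73 and 0.81). Among 33 odorant, 35 gustatory and 23 ionotropic receptors limma called no member with 8 arrays; with 7 arrays 1 gustatory receptor was higher, 1 lower and 1 ionotropic receptor lower (camera adjusted p = 0.053, 0.053 and 0.23 with 8 arrays, 0.78, 0.76 and 0.87 with 7). Or85b gave 0.69 ± 0.47 and Ir75b 0.08 ± 0.77, neither past the threshold.

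Detoxification genes also differed both ways. The glutathione transferase genes GstE6, GstE1, GstE9 and GstD9 were lower in sechellia, by log2 -3.60 ± 0.15, -2.93 ± 0.20, -1.77 ± 0.11 and -1.75 ± 0.16. Of 31 glutathione transferases 4 were lower and 3 higher with 8 arrays, and 7 lower and 8 higher with 7 (camera adjusted p = 0.33 and 0.76). Among cytochrome P450 genes, Cyp6g1, known for insecticide resistance, Cyp313a1 and Cyp6a20 were lower, at -2.08 ± 0.14, -1.93 ± 0.24 and -1.84 ± 0.23, and Cyp28d1 was higher by 1.19 ± 0.13. Cyp6a2 gave -1.07 ± 0.37 (adjusted p = 0.12) with 8 arrays and was lower at -1.54 with 7. Of 75 P450 genes 7 were higher and 7 lower with 8 arrays (10 and 8 adjusted over the list alone) and 11 higher and 18 lower with 7 (camera adjusted p = 0.92 and 0.61).

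Immune genes were split between the species. The antimicrobial peptide genes Mtk and DptB were higher in sechellia by log2 2.27 ± 0.14 and 2.39 ± 0.37, while Drsl4 and BomBc3 were lower, at -3.07 ± 0.21 and -2.40 ± 0.15. Of 18 antimicrobial peptides 3 were higher and 7 lower with 8 arrays (4 and 7 adjusted over the list alone) and 6 and 8 with 7 (camera adjusted p = 0.4 and 0.64). PGRP-SB1, a peptidoglycan recognition protein gene, was higher by 1.56 ± 0.14 and Tep4, a thioester protein gene, by 1.28 ± 0.25. Of 11 recognition genes 3 were higher and 1 lower with 8 arrays (5 and 1 adjusted over the list alone) and 7 and 3 with 7 (camera adjusted p = 0.17 and 0.52). Among sugar enzymes, the maltase genes Mal-A3 and Mal-A7 and the alpha-glucosidase gene tobi were higher by 2.21 ± 0.26, 2.06 ± 0.12 and 1.65 ± 0.13, and Mal-B1 was lower at -3.80 ± 0.21. Of 12 genes of the amylase and maltase list 6 were higher and 1 lower with 8 arrays, and 6 and 2 with 7 (camera adjusted p = 0.079 and 0.14). Of 11 clock genes cyc and tim were higher, by 1.75 ± 0.15 and 1.22 ± 0.25, with 4 higher and 1 lower with 7 arrays (camera adjusted p = 0.062 and 0.045; 0.77 and 0.54 with an estimated correlation). Lsp2, a serum protein gene, was higher by 1.79 ± 0.13, and the phototransduction arrestin gene Arr1 by 1.28 ± 0.28; Arr2 is the other of the 2 called of 12 head and eye markers (camera adjusted p = 0.053 and 0.34). Of 70 oxidative phosphorylation genes 30 were higher and 4 lower with 7 arrays, among them Cyt-c1 (0.86 ± 0.06) and ATPsynC (0.69 ± 0.05); with 8 arrays limma called no member (camera adjusted p = 0.58), and with 7 the list was higher (camera adjusted p = 0.0068, adjusted p = 0.75 with an estimated correlation), a call lost after median centring. Catsup, a regulator of dopamine synthesis, gave -0.04 ± 0.14 and RpL32 -0.22 ± 0.35, neither called.

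**Figure D2:**
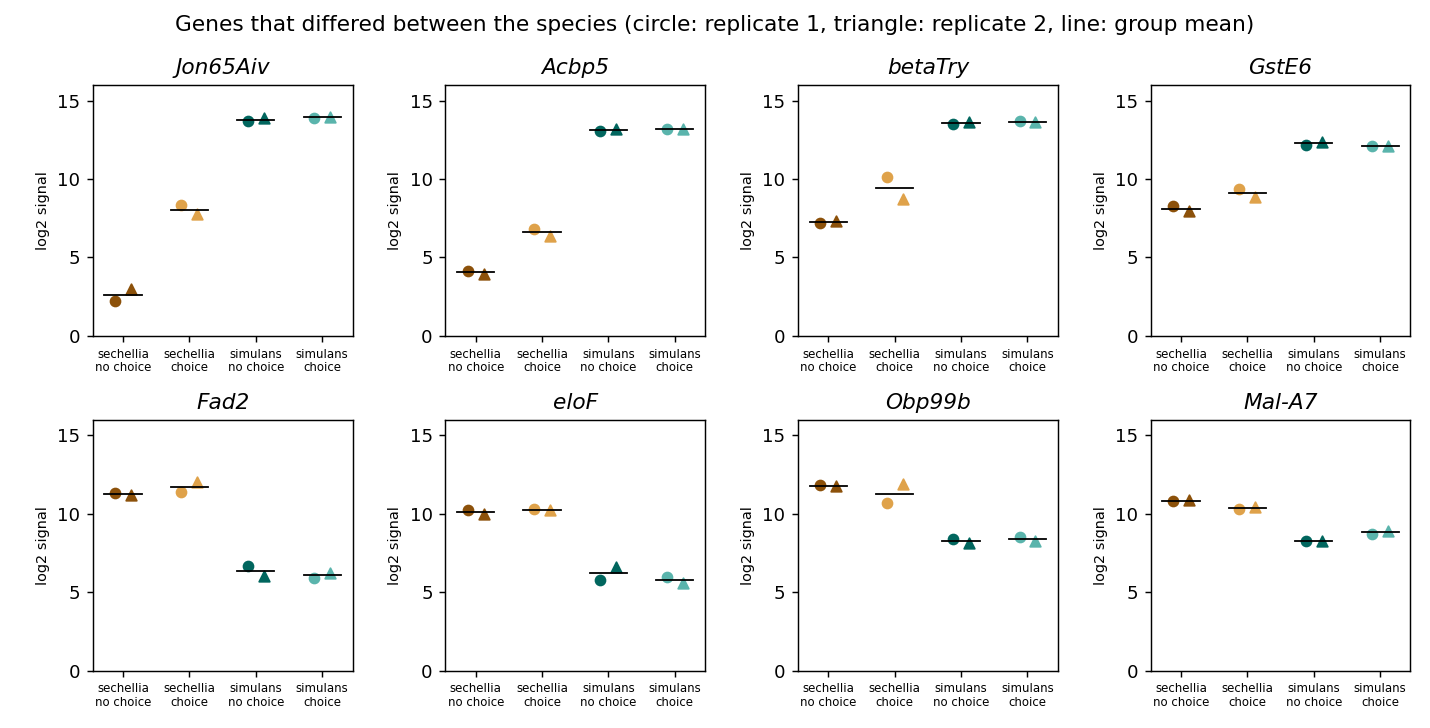
Log2 signal (vertical axis) of Jon65Aiv, Acbp5, betaTry, GstE6, Fad2, eloF, Obp99b and Mal-A7 in the 4 groups (horizontal axis), with circles for array 1, triangles for array 2 and a line at the group mean. Jon65Aiv, Acbp5, betaTry and GstE6 are lower in sechellia under both treatments and the other genes are higher.

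In all, 1297 of 13138 probe sets differed between the species with 8 arrays, 580 higher and 717 lower in sechellia, and 316 and 378 of these differed at least 2-fold. With 7 arrays 4276 differed, 2225 higher and 2051 lower, 472 and 536 of them at least 2-fold. The count was 8160 without array 2 of sechellia choice and between 472 and 503 without any of the 6 other arrays. Of 33 lists, 2 were called with 8 arrays and 5 with 7, against 17 without array 2 of sechellia choice and 6 without array 2 of simulans choice. None was called with an estimated correlation, for which 1 list with 8 arrays and 2 with 7 had an unadjusted p below 0.05, and fry called 8 and 21. Across 645 genes with 2 tested probe sets, the species differences of both probe sets correlated weakly, at Pearson r 0.171, so a difference in a gene named here rests on its probe set.

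The species also differed under each treatment by itself. The group means of the 2 treatments share no array, but both contrasts share 1 estimate of spread per probe set. Their calls are therefore not independent, and the numbers given below for independent calls are too low as a comparison. A probe mismatch would also recur under both treatments. A fit of only the arrays compared, which does not share that spread, called 3487 probe sets in no choice and 19 in choice. In no choice 554 probe sets differed with 8 arrays, 241 higher and 313 lower in sechellia, and 3705 with 7, 1908 higher and 1797 lower. In choice 544 differed with 8 arrays, 248 higher and 296 lower, and 2547 with 7, 1262 higher and 1285 lower. Of these, 298 were called in both treatments with 8 arrays, all in the same direction, where 22.9 would be shared by independent calls; with 7 arrays 1783 were shared, 1739 of them in the same direction, where 718 would be shared. Digestive trypsins and Jonah proteases were lower in both: in no choice 15 of 27 lower and 2 higher with 8 arrays (camera adjusted p = 1.1e-09; 0.26 with an estimated correlation), and in choice 10 lower and 3 higher (camera adjusted p = 0.0031; 0.69 with an estimated correlation). Vitelline membrane and chorion genes had a median log2 difference of -1.97 in no choice, with 10 of 16 lower (camera adjusted p = 1.6e-12; 0.65 with an estimated correlation), and -0.60 in choice, with 2 lower (camera adjusted p = 0.0057; 0.69 with an estimated correlation). With 7 arrays 14 were lower in no choice and 6 in choice. For no choice, the count was 3686 without array 2 of sechellia choice, 242 and 243 without a simulans choice array and between 107 and 119 without any of the 4 no choice arrays. For choice, it was 8980 without array 2 of sechellia choice, 50 and 52 without a simulans choice array and between 146 and 166 without any no choice array.

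In sechellia, single genes of digestion and of the eggshell were called higher in choice than in no choice with 8 arrays. Jon65Aiv rose by log2 5.44 ± 0.30 (n = 2 arrays per group, limma adjusted p = 0.0012), to signals of 320.4 and 214.2, far below its level in simulans. The 320.4 is on array 1, where the median probe-set signal was 316.7 and that of the Bacillus controls 128.85. On array 2 these were 129.8 and 12.3. Dim signals stood higher on array 1, so rises from low signals may be inflated there. Since the no choice signals of Jon65Aiv lie below the background controls, its rise over background is at least 3.40 with 7 arrays. With 8 arrays it is 3.69, which is no bound, because array 1 may inflate it. Acbp5 rose by 2.54 ± 0.21 (adjusted p = 0.0084). The chorion gene Cp16 rose by 1.83 ± 0.21 (adjusted p = 0.045). CG5568, CG2233, CG43333 and CG13114 rose by 3.31 ± 0.35, 2.57 ± 0.17, 2.04 ± 0.20 and 2.02 ± 0.17. Over background the rise of CG5568 was 2.31 with 8 arrays, which array 1 may inflate, and at least 1.96 with 7. The genes named in this paragraph are the 7 probe sets called with 8 arrays, and all were higher in choice. In limma 1865 had an unadjusted p below 0.05. The fit takes 1 spread per probe set from all 4 groups, so the wide spread of this pair is averaged with narrower ones. Fitted on only the arrays compared, limma called 0 (374 with an unadjusted p below 0.05). Without an intensity trend it called 0 (1370), and after median centring 1.

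With 7 arrays, 327 probe sets changed with choice in sechellia, 208 higher and 119 lower, where the choice group is its array 2. Of 16 vitelline membrane and chorion genes 13 rose and 1 fell (14 and 1 adjusted over the list alone), with a median log2 change of 1.37; yellow-g2 rose by 2.66 ± 0.12, Cp7Fc by 2.25 ± 0.10 and Cp18 by 1.71 ± 0.08. The list rose (camera adjusted p = 3.3e-20; 0.10 with an estimated correlation). With 8 arrays 1 member rose (9 rose and 1 fell adjusted over the list alone), at a camera adjusted p of 5.8e-06 (0.62 with an estimated correlation), and yellow-g2 and Cp7Fc gave 2.04 ± 0.35 (adjusted p = 0.17) and 1.71 ± 0.31 (adjusted p = 0.2). Of 27 digestive trypsins and Jonah proteases 11 rose and 1 fell with 7 arrays (13 and 2 adjusted over the list alone), among them Jon25Bii by 2.24 ± 0.09, Jon65Ai by 1.85 ± 0.09 and betaTry by 1.41 ± 0.10, and the list rose (camera adjusted p = 3.9e-10; 0.10 with an estimated correlation); with 8 arrays it also rose (camera adjusted p = 1.3e-07; 0.37 with an estimated correlation), with 1 member called. Without array 2 of sechellia choice, Jon65Ai was instead lower in choice, at -0.48. The female germline list was lower with 8 arrays as deposited (camera adjusted p = 0.023, or 0.62 with an estimated correlation, median log2 -0.29). Relative to all genes its median was -0.37 as deposited, but 0.02 after quantile normalisation and 0.04 after loess of these arrays. With 7 arrays it was not called, at a relative median of -0.03. There 5 of its 39 members fell, among them tor, a receptor tyrosine kinase of embryo patterning (-1.25 ± 0.10), and gcl (-0.43 ± 0.07). Yp1 gave 0.18 ± 0.12.

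With 7 arrays the antimicrobial peptide and P450 lists were higher in sechellia choice. Of 18 antimicrobial peptides 3 rose (9 adjusted over the list alone), with BomS2 up by log2 1.95 ± 0.27 and Mtk by 1.24 ± 0.10, and the list rose (camera adjusted p = 6.6e-06; 0.10 with an estimated correlation). PGRP-SB1 and PGRP-LB, of peptidoglycan recognition, rose by 1.51 ± 0.16 and 0.93 ± 0.17, the 2 called of 11 recognition genes (camera adjusted p = 0.29). Of 75 cytochrome P450 genes 5 rose (7 adjusted over the list alone), including Cyp6g1 by 1.12 ± 0.16, Cyp6a19 by 1.03 ± 0.15, Cyp9f2 by 0.98 ± 0.09 and Cyp4e2 by 0.93 ± 0.14 (camera adjusted p = 1.7e-04; 0.10 with an estimated correlation). Cyp9f2 was lower in choice, at -0.73, without array 2 of sechellia choice. Both lists also rose with 8 arrays (camera adjusted p = 0.028 for antimicrobial peptides and 5.8e-06 for P450; 0.62 for both with an estimated correlation), where limma called no member over all probe sets and 2 and 3 adjusted over the list alone. The antimicrobial peptides were not called after median centring of the 8 arrays, nor without array 2 of sechellia choice or array 1 of sechellia no choice. Their call with 8 arrays thus depends on scaling and on single arrays. Relative to all genes their median with 8 arrays was 0.27 as deposited and 0.39 after quantile normalisation. With array 2 as the only choice array it was 0.39 as deposited. The odorant-binding protein genes Obp99a and Obp56e rose by 1.39 ± 0.18 and 0.93 ± 0.18 with 7 arrays, 2 of 3 called among 22 (camera adjusted p = 0.27), and the perilipin gene Lsd-1 rose by 0.95 ± 0.09. Among the largest changes, CG6295 rose by 3.08 ± 0.10, Nepl14 by 2.98 ± 0.50 and CG4213 by 2.87 ± 0.41, and alka and CG4229 fell, with log2 changes of -3.58 ± 0.55 and -2.95 ± 0.34; alka fell below the background control, where its change is -2.95 or lower. Catsup gave -0.04 ± 0.13, Or85b 0.48 ± 0.47 and Osi6 -1.52 ± 0.74 (-1.18 over background), none called.

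The proteasome and DNA replication lists fell with 7 arrays (camera adjusted p = 0.0037 and 0.0077; 0.19 and 0.20 with an estimated correlation), at median log2 changes of -0.10 and -0.17, and oxidative phosphorylation rose (camera adjusted p = 0.032; 0.80 with an estimated correlation), at 0.09 (a call lost after median centring and after quantile normalisation), with no member called in any of these 3. With 8 arrays as deposited, oxidative phosphorylation was called in the opposite direction (camera adjusted p = 0.0073, or 0.68 with an estimated correlation, median log2 -0.38). Relative to all genes its median there was -0.46 as deposited, but 0.11 after quantile normalisation and 0.11 after loess. Lists called in sechellia numbered 18 of 33 with 8 arrays, 11 up and 7 down, and 7 with 7 arrays, 5 up and 2 down. Of the 18, 13 were also called after median centring and 9 after quantile normalisation, and of the 7, 6 were in each. The median relative to all genes changed sign under another scaling for 5 of the 18 and 0 of the 7. None was called with an estimated correlation, where 1 list with 8 arrays and 6 with 7 had an unadjusted p below 0.05, and fry called 2 and 7. The called probe sets numbered 8671 without array 2 of sechellia choice, 1 without a sechellia no choice array and 2 without a simulans array.

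**Figure D3:**
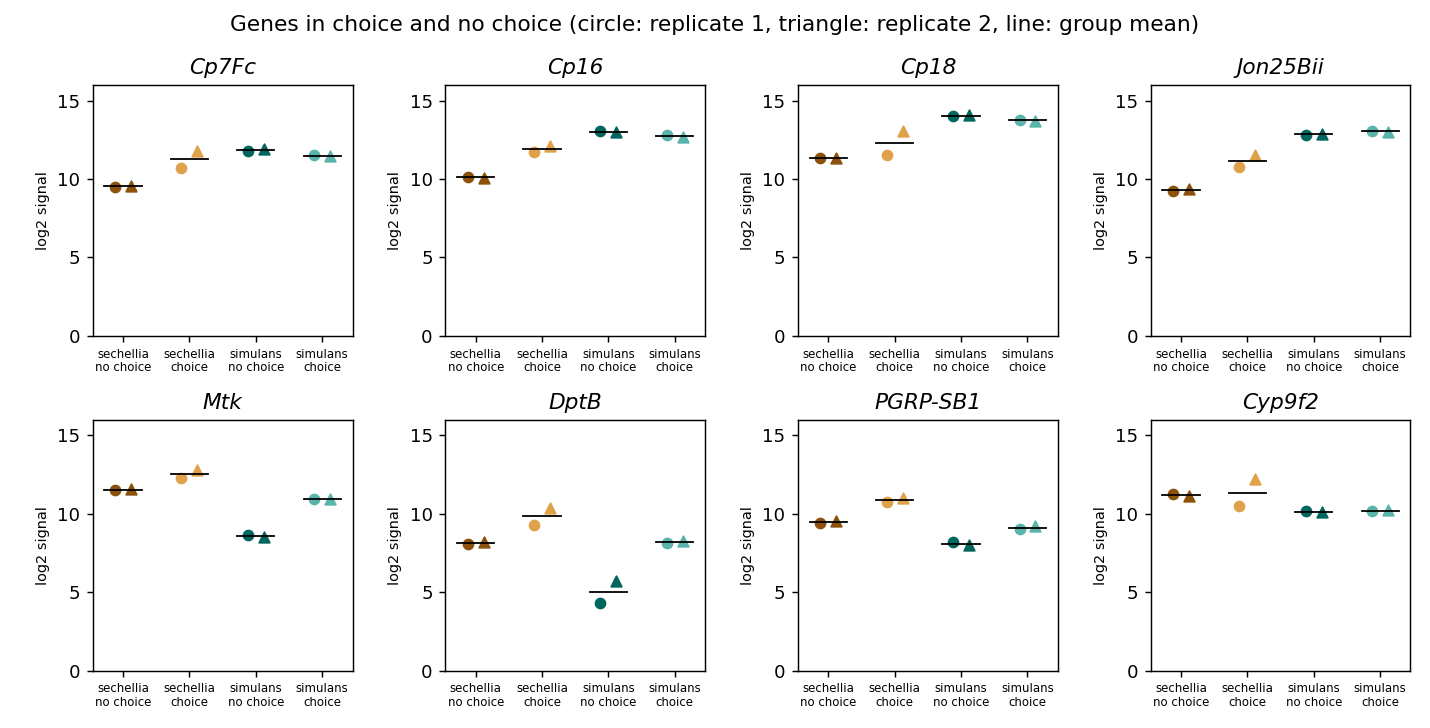
Log2 signal (vertical axis) of Cp7Fc, Cp16, Cp18, Jon25Bii, Mtk, DptB, PGRP-SB1 and Cyp9f2 in the 4 groups (horizontal axis), with circles for array 1, triangles for array 2 and a line at the group mean. The eggshell genes are lower in sechellia no choice than in the other groups, and Mtk and DptB are higher in choice in both species.

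**Figure D4:**
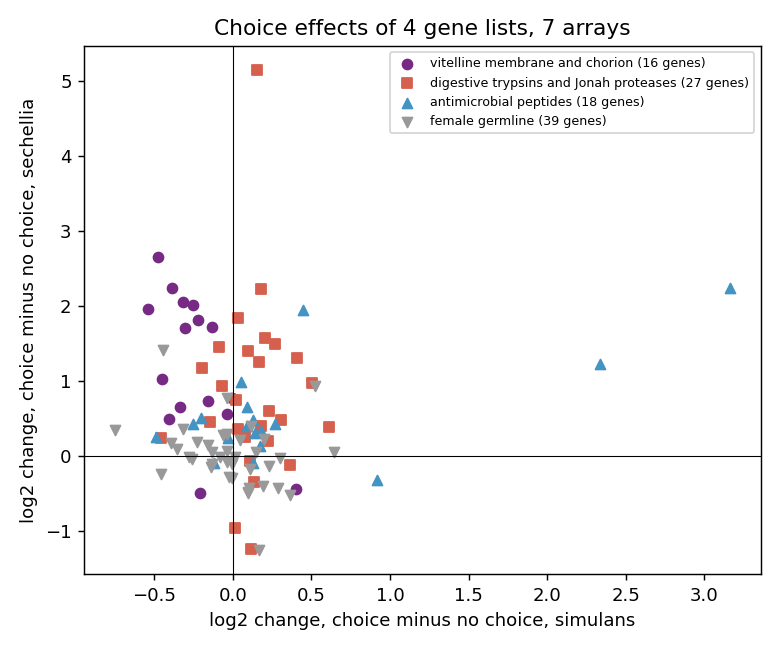
Log2 change with choice in simulans (horizontal axis) and in sechellia (vertical axis), 7 arrays, 1 point per gene, for 16 vitelline membrane and chorion genes, 27 trypsins and Jonah proteases, 18 antimicrobial peptides and 39 female germline genes. Most eggshell genes lie above 0 in sechellia, with a median of 1.37, and below 0 in simulans, with a median of -0.28.

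In simulans, the antimicrobial peptide gene Mtk rose by log2 2.34 ± 0.20 with choice (n = 2 arrays per group, limma adjusted p = 0.037). It was the 1 probe set called with 8 arrays, of 243 with an unadjusted p below 0.05. It was not called after median centring, after quantile normalisation, without an intensity trend, in a robust fit or with the replicate block. With 7 arrays, which are the same 4 simulans arrays tested against a smaller spread, 36 were called, 28 higher and 8 lower. Among them, edin, an immune-induced gene, rose by 4.05 ± 0.51, DptB by 3.16 ± 0.39, and the stress peptide gene TotC by 2.02 ± 0.23, and PGRP-SB1 was higher too. Of 18 antimicrobial peptides 2 rose with 7 arrays (3 rose and 1 fell adjusted over the list alone), and the list rose with 8 and with 7 (camera adjusted p = 0.0086 and 0.025; 0.30 and 0.35 with an estimated correlation).

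The amylase and maltase list also rose in simulans choice, a call lost after median centring of the 8 arrays (camera adjusted p = 0.0021 with 8 arrays and 0.004 with 7; 0.30 and 0.35 with an estimated correlation), with Mal-A1 up by log2 0.84 ± 0.11 with 7 arrays (adjusted p = 0.058 after median centring of these; 4 of 12 adjusted over the list alone), Mal-A7 at 0.55 ± 0.11 (adjusted p = 0.08) and tobi at 0.54 ± 0.09 (adjusted p = 0.061). The insulin and nutrient signalling list rose (camera adjusted p = 0.0021 and 3.6e-04; 0.30 and 0.35 with an estimated correlation) with 1 of 19 members called adjusted over the list alone; the insulin receptor gene InR gave 0.76 ± 0.44. Vitelline membrane and chorion genes were lower as a list (median log2 -0.28; camera adjusted p = 0.0035 and 1.1e-05; 0.97 and 0.35 with an estimated correlation): with 7 arrays yellow-g fell (-0.54 ± 0.08), 9 of 16 fell adjusted over the list alone, and 1 member rose, Cp190, which is a centrosomal protein gene (0.40 ± 0.06). Ribosomal proteins fell as a list (median -0.08; camera adjusted p = 0.0035 and 2.3e-04; 1 and 0.64 with an estimated correlation). With 7 arrays the trypsin list rose and the proteasome list fell too (camera adjusted p = 0.033 and 0.03; 0.35 for both with an estimated correlation). CG14125 and CG13324 rose by 1.79 ± 0.14 and 1.35 ± 0.19, and bard, Cth, a cystathionine gamma-lyase gene, and Jhbp5 fell, with log2 changes of -2.58 ± 0.37, -0.79 ± 0.11 and -0.58 ± 0.08. Obp56e, Catsup and Osi6 gave 0.17 ± 0.14, 0.07 ± 0.11 and 0.91 ± 0.60, none called.

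For simulans, 30 probe sets were called without array 2 of sechellia choice, and none without any of the 6 other arrays, where 117 to 140 had an unadjusted p below 0.05 in limma. Lists called numbered 5 of 33 with 8 arrays and 7 with 7. Of the 5, none was called after median centring, where 6 lists had an unadjusted p below 0.05 in camera, and all 5 were after quantile normalisation. Of the 7, all were called after both and 6 after loess, where the proteasome was lost. The ribosomal and eggshell calls were lost without array 2 of simulans no choice, and the ribosomal call without array 2 of simulans choice. None was called with an estimated correlation, where 3 lists with 8 arrays and 1 with 7 had an unadjusted p below 0.05, and fry called 0 and 2.

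Averaged over species, choice was higher than no choice for Jon65Aiv by log2 2.80 ± 0.21 (n = 4 arrays per treatment, limma adjusted p = 0.014). Over background this rise was 1.92 with 8 arrays, which array 1 of sechellia choice may inflate, and at least 1.77 with 7. Mtk was higher by 1.67 ± 0.14 (limma adjusted p = 0.017) and CG2233 by 1.24 ± 0.12 (limma adjusted p = 0.031). Jon65Aiv and CG2233 were not called in simulans, and Mtk passed in simulans with 8 arrays and in both species with 7. PGRP-SB1, 1.20 ± 0.14, and Acbp5, 1.30 ± 0.15, did not pass with 8 arrays (adjusted p = 0.068 for both). With 7 arrays 192 were called, 157 higher and 35 lower; edin rose by 3.42 ± 0.41, DptB by 2.70 ± 0.31, CG6295 by 1.66 ± 0.06, the lysozyme gene LysS by 1.26 ± 0.17, PGRP-SB1 by 1.26 ± 0.10, Jon25Bii by 1.21 ± 0.06, Cp7Fc by 0.93 ± 0.06 and Cyp6g1 by 0.65 ± 0.11. Eggshell genes (9 of 16 higher), trypsins and Jonah proteases (12 of 27 higher, 1 lower), antimicrobial peptides (4 of 18 higher) and P450 genes (2 of 75 higher, 11 adjusted over the list alone) rose as lists with 7 arrays (camera adjusted p = 3.3e-16, 2.3e-11, 7.2e-07 and 4.5e-04; 0.11 for each with an estimated correlation). Without array 2 of sechellia choice the eggshell genes and the antimicrobial peptides were not called. Amylase and maltases and juvenile hormone and ecdysone genes rose too (camera adjusted p = 0.015 and 0.02; 0.31 and 0.26 with an estimated correlation), and ribosomal proteins and the proteasome fell (camera adjusted p = 0.02 and 5.5e-05; 0.57 and 0.11 with an estimated correlation), the ribosomal call being lost after quantile normalisation and after loess.

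The averaged test called 3 probe sets with 8 arrays, 7303 without array 2 of sechellia choice, 1 without array 2 of sechellia no choice and none without any of the 5 remaining arrays, where limma found 269 to 389 with an unadjusted p below 0.05. Lists called numbered 16 with 8 arrays, 10 up and 6 down, and 8 with 7. Of the 16, 11 were also called after median centring and 8 after quantile normalisation, and of the 8, 8 and 7. The median relative to all genes changed sign under another scaling for 4 of the 16 and 0 of the 8. None was called with an estimated correlation, where 2 lists with 8 arrays and 6 with 7 had an unadjusted p below 0.05, and fry called 3 and 8.

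The interaction tests whether choice acted differently in the 2 species. Jon65Aiv changed by log2 5.29 ± 0.42 more in sechellia than in simulans (n = 2 arrays per group, limma adjusted p = 0.022). Over background this was 3.53 more with 8 arrays, which array 1 of sechellia choice may inflate, and at least 3.24 more with 7. CG2233 changed by 2.66 ± 0.24 more in sechellia (limma adjusted p = 0.028). Neither gene was called with 8 arrays after median centring, without an intensity trend or with the replicate block. CG2233 stood at a mean log2 signal of 8.16 ± 0.08 (SD, n = 2) in sechellia no choice, 10.73 ± 0.15 in sechellia choice, 12.40 ± 0.05 in simulans no choice and 12.31 ± 0.11 in simulans choice. These 2 were called with 8 arrays, of 898 with an unadjusted p below 0.05, and 366 with 7, 176 higher and 190 lower. With 7 arrays the eggshell genes yellow-g2, Vm32E, Cp7Fc, yellow-g and Cp18 had positive interactions, of 3.14 ± 0.16, 2.88 ± 0.31, 2.63 ± 0.12, 2.51 ± 0.12 and 2.01 ± 0.10, and 13 of 16 members were higher and 1 lower (camera adjusted p = 1.4e-19; 0.21 with an estimated correlation). Of 27 trypsins and Jonah proteases 10 were higher and 1 lower, including Jon25Bii (2.05 ± 0.11) and Jon65Ai (1.82 ± 0.11; -0.52 without array 2 of sechellia choice), with a camera adjusted p of 2.5e-05 (0.21 with an estimated correlation). The interactions of CG6295 and Jhbp5 were 2.86 ± 0.13 and 2.43 ± 0.13. Those of Mtk, Mal-A7, tobi, Lsp2 and TotC were negative, at -1.10 ± 0.13, -0.92 ± 0.17, -1.03 ± 0.14, -1.01 ± 0.16 and -1.83 ± 0.37.

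P450 genes and oxidative phosphorylation were also higher in the interaction with 7 arrays, and DNA replication lower (camera adjusted p = 0.024, 0.04 and 0.03; 0.30, 0.78 and 0.37 with an estimated correlation). The oxidative phosphorylation call was lost after median centring and after quantile normalisation, and its median of 0.12 was -0.37 with 8 arrays, where it was not called. Relative to all genes the median with 8 arrays was -0.43 as deposited, but 0.11 after quantile normalisation and 0.10 after loess. The DNA replication call was lost after loess. The lists called numbered 12 with 8 arrays and 5 with 7. Of the 12, 9 were also called after median centring and 4 after quantile normalisation. None was called with an estimated correlation, where 1 list with 8 arrays and 4 with 7 had an unadjusted p below 0.05, and fry called 0 and 5. The called probe sets numbered 7300 without array 2 of sechellia choice, 1 without array 2 of sechellia no choice and none without any of the 5 remaining arrays, where limma found 347 to 452 with an unadjusted p below 0.05.

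Across all 13138 probe sets, which are not independent replicates, the choice effects of the 2 species correlated at Pearson r -0.030 and Spearman rho -0.019 with 8 arrays and -0.0004 and -0.025 with 7. With 7 arrays 3 probe sets were called in both species in the same direction and 5 in opposite directions. Among the 327 calls in sechellia, 136 had the same sign in simulans, and among the 36 calls in simulans, 19 had the same sign in sechellia. The SD of the log2 changes was 0.84 in sechellia with 8 arrays, 0.58 with 7, and 0.47 in simulans. The first includes array 1 of sechellia choice, and the second rests on 1 choice array where simulans has 2. These SDs are therefore not like for like and do not show a wider response in sechellia. Noise between arrays also weakens such correlations.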

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

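The tests of RNA degradation, of background, of the share of simulans RNA, of array 2 alone and of the share of ovary were chosen only after the results they weigh were seen.

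Array 1 of sechellia choice stood apart, with correlations of 0.674 to 0.720 with the others, and its Bacillus control probe sets, outside the measured fly genes, had a median signal of 128.85, 4.59 times the highest of the other arrays. That it is a simulans sample is argued against by its correlations, 0.712 to 0.720 with each sechellia array and 0.674 to 0.696 with each simulans array, and by its Jon65Aiv signal of 320.4 against 13031 to 15647; its median position between sechellia (0) and simulans (1) over 226 probe sets at least 4-fold apart was 0.125, with quartiles of -0.266 to 0.535. Degraded RNA stays open: the mean log2 ratio of 3' over 5' signal of 4 control genes was 0.798, within the 0.602 to 0.938 of the others, but the array's narrow range shrinks such a ratio, and after quantile normalisation it was 0.997 against 0.582 to 0.935. A raised background or weak hybridisation also stays open as a candidate explanation: it needs high controls, but the 128.85 was seen before it was proposed and so does not test it, and whether control RNA was added to this sample is not given in the sources used here. The cre control probe sets had a median signal of 11962 on array 1, against 18063 to 23147 on the others. Its maximum signal was 17104, against 27991 to 34157. Neither value was set as a test of raised background or weak hybridisation, so they do not decide it. No biological explanation was tested.

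Eggshell genes, taken here without Cp190 and Cp110, were higher in choice than in no choice in sechellia. Whether array 2 alone differs stays open. On array 1, scaled by quantile normalisation, the full list, with Cp190 and Cp110, lay log2 1.18 above no choice on average. This was at percentile 100 of 10000 lists matched on signal (middle range -0.61 to 0.25). The matching used the mean over all arrays and not the no choice level, which is low for these genes, so it cannot decide. On array 1, 14 of 14 eggshell genes lay above both no choice arrays. The same held on array 2, where the pattern was seen. Simulans RNA in the choice sample is argued against, since 178 other probe sets at least 4-fold lower in sechellia need a median share of 9.45% (quartiles 2.09 to 33.8), against 60.1% for the eggshell genes (lower quartile 47.4), and Jon65Aiv, Acbp5 and betaTry need 1.40%, 0.743% and 2.12%. A larger share of ovary is argued against by the female germline list, with a median log2 change of -0.0017 (quartiles -0.20 to 0.21, 39 genes) against 1.72 for the eggshell genes, although more egg chambers at the stages that make the shell remain possible. An effect of choice on these genes may be a hypothesis to follow up, with the flies' age and mating not given in the sources used here and the 2 no choice arrays shared by every value above.

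Many genes differed between the species, on probes made for D. melanogaster. If mismatch to the probes acted on each probe set by itself and were the sole source, 2 probe sets of a gene would agree no better than random pairs; across 645 genes they correlated at r 0.171 (rho 0.161), above the 0.0737 that bounds the middle range of 1000 random pairings. Of 103 genes with both probe sets called, 73 went in the same direction and 30 in opposite directions. Mismatch of that kind may therefore not be the sole source. Mismatch shared by the probe sets of a gene, mismatch for any gene by itself and a true difference between the species stay open.

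The remaining results passed the interaction test with 8 arrays. Jon65Aiv had an interaction of log2 5.29 and CG2233 of 2.66. Over background that of Jon65Aiv was 3.53 with 8 arrays, which array 1 of sechellia choice may inflate, and at least 3.24 with 7. Among the lists, 12 were called by camera with the preset correlation, none with an estimated one (lowest adjusted p 0.68; 1 at an unadjusted p below 0.05) and none by fry (4). For these the median interaction was 1.46 for ionotropic receptors, 1.30 for vitelline membrane and chorion, 1.10 for gustatory receptors, 0.98 for male reproductive markers, 0.86 for odorant receptors, 0.82 for cytochrome P450, 0.80 for digestive trypsins and Jonah proteases and 0.76 for cuticle proteins. It was -0.46 for the proteasome, -0.45 for flight and body muscle, -0.43 for DNA replication and cell cycle and -0.39 for heat shock proteins. Of these, 9 were also called after median centring and 4 after quantile normalisation, and the median relative to all genes changed sign for 1, muscle, under another scaling. With 7 arrays, 4 of these 12 lists were called: vitelline membrane and chorion (median 1.67), trypsins and Jonah proteases (0.60), P450 (0.29) and DNA replication (-0.12). The other 8 were not, with medians of 0.29 for ionotropic, 0.24 for gustatory and -0.21 for odorant receptors, 0.01 for male markers, 0.14 for cuticle proteins, -0.07 for the proteasome, 0.07 for muscle and -0.20 for heat shock proteins, so their calls with 8 arrays depend on array 1 of sechellia choice.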

How the results depend on the processing

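Tests with 7 arrays and the crossed block were chosen after seeing the data; the other alternatives were planned. Signal over background limits what can be called: 30% of probe sets, those below a geometric mean signal of 49.9, were not tested, and on array 1 of sechellia choice the 10th percentile stood at 81.0. For the 188 results of named genes, 4098 values under alternatives were computed. Of these, 3358 stayed on the same side of the threshold, counting changes of sign where neither value passed it. Another 392 newly passed it and 342 no longer passed it, in the same direction. The other 6 reversed, which here means a change of sign with a pass in either fit. Of 100 called with 8 arrays, none reversed; those still called in the same direction numbered 49 after median centring, 69 without an intensity trend, 84 after quantile normalisation, 87 of 87 without suffixed probe sets, 89 with the replicate block, 92 with array weights, 95 in a robust fit, 98 with the offset, 99 without a filter, 95 of 95 with the stricter filter, 100 after loess, 62 to 65 without any of the 6 arrays outside sechellia choice and 100 without either sechellia choice array. Of 168 called with 7 arrays, all kept their direction in the 3 scalings and 161 (median centring), 168 (quantile) and 168 (loess) were called; median centring lost Yp3 between species, Cyp6g1 by averaged choice, PGRP-LB and Obp56e in sechellia and Mal-A1, Jhbp5 and Cp190 in simulans. The 6 reversals were Jon65Ai and Cyp9f2 in sechellia and Jon65Ai in the interaction, at -0.48, -0.73 and -0.52 without array 2 of sechellia choice against 1.85, 0.98 and 1.82 without array 1. The others were Yp2 between species (0.14 with quantile normalisation and 0.21 with loess, 7 arrays, from -0.01) and Desat1 (0.14 with loess, 7 arrays, from -0.08). Where not said otherwise, the cause was not tested.

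Median centring moved the median log2 difference of all probe sets from 0.14 to -0.30 for the species difference averaged over treatments, from 0.20 to -0.60 for it in choice, from 0.08 to -0.34 for the averaged choice effect, from 0.19 to -0.59 in sechellia and from 0.14 to -0.59 for the interaction. It gave 419 calls for the averaged species difference (92 higher, 327 lower), 117 in no choice (29 and 88), 103 in choice (19 and 84), 0 for the averaged choice effect in limma (372 with an unadjusted p below 0.05), 1 in sechellia, 0 in simulans (247) and 0 for the interaction (474). With 7 arrays its split was 1490 and 2670 for the averaged species difference, 1456 and 2040 in no choice, 738 and 1784 in choice, 85 and 90 for the averaged choice effect, 150 and 316 in sechellia, 17 and 10 in simulans and 111 and 184 for the interaction. Quantile normalisation gave 7 for the averaged choice effect, 20 in sechellia (18 higher, 2 lower), 0 in simulans (279) and, with 7 arrays, 67 in simulans. Cyclic loess gave 2126 for the averaged species difference, 1173 in no choice, 1183 in choice, 23 for the averaged choice effect, 56 in sechellia, 2 in simulans and 24 for the interaction. Without an intensity trend there were 841, 236 and 138 for the 3 species differences, 0 for the averaged choice effect (713), 0 in sechellia (1370), 0 in simulans (312) and 0 for the interaction (752); with 7 arrays 2278 in no choice, 1176 in choice, 6 for the averaged choice effect, 35 in sechellia, 7 in simulans and 0 for the interaction (1840). A robust fit gave 0 in simulans (238). Without a dim filter simulans had 2, and with 7 arrays 7, the averaged choice effect 125 and the interaction 231. Without suffixed probe sets the averaged choice effect had 5. Array weights gave 361 higher and 667 lower for the averaged species difference, 3768 in no choice, 96 in choice, 3 in sechellia, 157 in simulans (98 higher, 59 lower) and 9 for the interaction. A fit of only the arrays compared gave 3487 in no choice, 19 in choice, 0 in sechellia (374) and 16 in simulans. The fits of no choice and of simulans leave out array 1 of sechellia choice by construction.

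The numbers of the arrays come only from their titles. Deviations of same-numbered arrays from their group means correlated between -0.12 and 0.05, which gives no sign that equal numbers pair the samples. The replicate block gave 313 for the species difference in choice, 4 for choice in sechellia, 0 in simulans (193) and 0 for the interaction (793), and 6 lists between species; it gave 1047 for the averaged species difference, 412 in no choice and 2 for the averaged choice effect. Since sechellia and simulans choice correlated at -0.12, the numbers were also crossed, which gave 334 in choice.

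Leaving out each array in turn gave 472 to 8160 calls for the averaged species difference, 107 to 3705 in no choice, 50 to 8980 in choice, 0 to 7303 for the averaged choice effect, 1 to 8671 in sechellia, 0 to 36 in simulans and 0 to 7300 for the interaction. The lists called ranged from 2 to 17 between species, 8 to 19 by averaged choice, 7 to 19 in sechellia, 3 to 7 in simulans and 5 to 18 for the interaction, and the correlation of choice effects from -0.068 to 0.019. Without array 1 or array 2 of sechellia choice the wide spread of this pair leaves the fit, which raises the counts by construction.

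For the lists, camera with an estimated correlation called 0 in each of the 5 comparisons with 8 and with 7 arrays, with 1 to 6 lists at an unadjusted p below 0.05. Fry called 8 between species (21 with 7 arrays), 3 by averaged choice, 2 in sechellia, 0 in simulans (4 at an unadjusted p below 0.05; 2 called with 7 arrays) and 0 for the interaction (4). Median centring called 9 between species (3 with 7 arrays) and 0 in simulans (6). Quantile normalisation called 9 by averaged choice, 9 in sechellia and 4 for the interaction. Without a dim filter 4 were called between species. The correlation of choice effects moved by less than 0.1 in every alternative run.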

Other observations

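The tests in this part with 7 arrays were chosen only after the results with 8 were seen. Hormone-related and stress genes also differed between the species, averaged over treatments with 8 arrays. Of 36 juvenile hormone and ecdysone genes 4 were higher in sechellia and 2 lower (9 and 6 with 7 arrays; camera adjusted p = 0.73 and 0.7). The juvenile hormone binding protein family members Jhbp12, Jhbp11 and Jhbp13 were higher by log2 1.72 ± 0.22, 1.35 ± 0.15 and 0.96 ± 0.13, and Jhbp5 was lower at -1.26 ± 0.16. The stress peptide gene TotC was higher by 1.94 ± 0.34, 1 of 4 Turandot genes (2 with 7 arrays; camera adjusted p = 0.26 and 0.64). The chaperone genes Hsp110, Hsc70-1 and DnaJ-1 were lower, at -0.90 ± 0.13, -0.74 ± 0.19 and -0.64 ± 0.15, the 3 called of 14 heat shock proteins (1 higher and 3 lower with 7 arrays; camera adjusted p = 0.25 and 0.64). Among 19 insulin and nutrient signalling genes 2 were higher and 3 lower (5 and 4 with 7 arrays; camera adjusted p = 0.87 and 0.81): Pepck1, of gluconeogenesis, was higher by 1.37 ± 0.21, and AMPKalpha and Sesn, of energy and nutrient sensing, were lower at -1.06 ± 0.17 and -0.97 ± 0.16. Of 26 UDP-glycosyltransferases 1 was higher and 3 lower (5 and 4 with 7 arrays; camera adjusted p = 0.75 and 0.88), with Ugt35C1 at -2.20 ± 0.26 and Ugt49B1 at 0.93 ± 0.15. Of 12 carboxylesterases 3 were higher and 1 lower (3 and 3 with 7 arrays; camera adjusted p = 0.3 and 0.64), with alpha-Est2 at -1.94 ± 0.32 and alpha-Est7 at 0.98 ± 0.15. In lipid handling the lipase gene mag was lower at -1.59 ± 0.35 and the fatty acid transporter gene Fatp3 was higher by 0.61 ± 0.11.

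With 8 arrays, single members of further lists differed between the species, and camera called none of these lists with 8 or with 7 arrays. Of 26 muscle genes 2 were higher and 2 lower (10 and 2 with 7 arrays; camera adjusted p = 0.74 and 0.14), with bt and TpnC41C at log2 0.92 ± 0.20 and 0.65 ± 0.14 and fln at -0.82 ± 0.20. Of 23 neuronal genes 1 was higher, unc-13 at 1.40 ± 0.35, and 1 lower, nrv2 at -0.90 ± 0.22 (5 and 2 with 7 arrays; camera adjusted p = 0.25 and 0.64). Of 9 dopamine pathway genes 1 was higher and 2 lower with 7 arrays, and limma called none with 8 (camera adjusted p = 0.81 and 0.76). Of 7 fat body and haemolymph genes 1 was higher and 2 lower (1 and 3 with 7 arrays; camera adjusted p = 0.73 and 0.74), with Sgp at -1.14 ± 0.11. Of 31 proteasome genes 2 were higher, Prosbeta6 at 0.82 ± 0.20 and Rpt4 at 0.71 ± 0.15 (9 higher and 2 lower with 7 arrays; camera adjusted p = 0.76 and 0.21). Of 104 ribosomal proteins 1 was higher and 5 lower (12 and 18 with 7 arrays; camera adjusted p = 0.053 and 0.64), among them the mitochondrial mRpL49 at -0.65 ± 0.11. Of 31 genes of DNA replication and cell cycle 2 were lower, the mitotic genes Klp61F at -0.82 ± 0.15 and Incenp at -0.57 ± 0.11 (8 higher and 11 lower with 7 arrays; camera adjusted p = 0.16 and 0.67). Of 70 cuticle proteins 1 was higher and 3 lower (5 and 9 with 7 arrays; camera adjusted p = 0.46 and 0.66), with TwdlN at -1.44 ± 0.31. Of 28 male reproductive markers 1 was lower (3 with 7 arrays; camera adjusted p = 0.3 and 0.81); bol, a testis gene, gave -0.08 ± 0.14 and rdgB, a head marker, -0.17 ± 0.13, neither called.

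Other groupings of the same arrays were tested with a fit of 2 groups. For the averaged species difference that fit called 1138 probe sets with 8 arrays and 3448 with 7. The highest of the other splits was 0 in limma, and 1 of 35 splits, the real one, was as large, with 8 and with 7 arrays. If the arrays are separate samples this share is under 0.05, which speaks against chance but does not exclude it. It is the smallest share these splits can give. A wrong split also puts the species difference into the spread, which holds down the other counts. If the 2 arrays of a group repeat the same RNA, which the labels leave open, 4 samples remain and their splits are too few for a share under 0.05. For the averaged choice effect the real split gave 0 with 8 and with 7 arrays (550 and 1259 with an unadjusted p below 0.05) and the highest other was 0. The 18 of 18 splits as large in each are too few for a share under 0.05. For lists between species, the real split called 2 with 8 arrays and 35 of 35 splits called as many. The highest other was 17, several times the real count, and the median of the others was 14. Without array 1 of sechellia choice that median was 3, so many of these calls depended on that array. With 7 arrays the real split called 4 and the highest other 6, and 12 of 35 were as large, so chance cannot be excluded. For lists by averaged choice the real split called 16 with 8 arrays and the highest other 17, with 5 of 18 as large, and 9 with 7 arrays with the highest other 7, where 1 of 18 was as large; these splits are too few for a share under 0.05.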
